A study of Mus musculus with 3 samples.

How the data were processed

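RNA was measured in CD4+CD25- T cells purified from spleen and lymph node of female BALB/c mice that lacked both Stat6, the transcription factor through which IL-4 drives Th2 cells, and T-bet (gene Tbx21), the transcription factor of Th1 cells. The cells were stimulated for 2 days with plate-bound anti-CD3 at 5 µg/ml and anti-CD28 at 1 µg/ml. Cytokines were added in 3 ways: TGFβ alone at 5 ng/ml, IL-6 at 10 ng/ml with IL-23 at 10 ng/ml, or IL-6 at 10 ng/ml with TGFβ at 5 ng/ml. Each condition was measured on 1 array, so there were no replicates. Biotin-labelled cRNA was prepared from total RNA and hybridized to Affymetrix mouse arrays, per the labels' protocols.

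The deposited values are linear intensities, 1 per probe set and array. The software that summarized the probes, the scaling and the background correction are not given in the sources used here. The deposited intensity differed between arrays as a whole, with medians of 35.8 on the TGFβ array, 17.8 on the IL-6/IL-23 array and 28.1 on the IL-6/TGFβ array over 45037 probe sets. The median of 18 hybridization control probe sets differed in the same order, at 1072, 626 and 825. For arrays, the number of arrays limits the precision, and here it was 1 per condition.

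The following choices were made before the data were examined: the comparisons, the between-array normalization, the floor, the 2-fold rule, the rule for the genes named, 30 gene lists and 10 alternative settings. Because array medians differed by more than 10%, the rule called for quantile normalization of log2 intensities (limma 3.58.1 in R 4.3.3) after 64 control probe sets of 45101 were left out. Quantile normalization gives all arrays the same distribution, so a real difference in total mRNA between conditions is removed. Of the 45037 probe sets, 34945 carried 1 gene symbol, 932 carried several genes and were not used for genes, and 9160 were unnamed here. Entrez identifiers of 34741 probe sets matched the RefSeq gene table of GRCm38.p6, and this renamed 0 symbols. The named probe sets stood for 18193 genes, and a gene was represented by its probe set with the highest mean over the 3 arrays.

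The floor was the 95th percentile of 78 probe sets of genes restricted to tissues such as liver, muscle, lens or testis. It lay at a normalized intensity of 46.5, or 5.54 on the log2 scale. Lower values were raised to it and have no order among themselves. A ratio with 1 array at the floor is a lower bound, and a ratio with both at the floor was not read for single genes. In medians of gene lists and of random lists, a gene above the floor on the third array alone entered as 0. On each array 39.8% of probe sets were above the floor, and 9895 genes were above it on at least 1 array. A gene was counted as higher or lower when its ratio was at least 2-fold with the brighter array above the floor. Normalized intensities are in arbitrary units, and probe sets of different genes cannot be set against each other.

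The only error that could be estimated is the spread of log2 ratios between the brightest probe sets of the same gene. Its SD for 1 probe set was taken from the median absolute deviation, which gives little weight to outlying probe sets. This SD was 0.23 for IL-6/TGFβ over TGFβ (4007 genes), 0.29 for IL-6/TGFβ over IL-6/IL-23 (3960 genes) and 0.31 for IL-6/IL-23 over TGFβ (3974 genes). The plain SD was larger, at 0.26, 0.33 and 0.34, and the spread named below is the smaller one. The spread covers differences between probe sets and leaves out those between cultures, mice and arrays. Unchanged arrays were simulated 1000 times with normal noise sized to the smaller SD, sharing arrays as the real comparisons do. Such noise holds no outlying probe sets.

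Genes named in the text followed a fixed rule. It took Stat6, Tbx21 and the IL-10 and IL-17 genes on every array. For both comparisons with the IL-6/TGFβ array it took the 10 largest and 10 smallest ratios measured on both arrays, leaving out a gene with another probe set of opposite sign, and ranked apart the 5 largest bounds per direction. For the remaining pair it took 5 genes per direction, for genes higher or lower in both comparisons 10 per direction, and from each gene list up to 4 members with the largest ratios. Genes outside the rule are said to have been chosen after their values were seen. A list's median log2 ratio was set against the medians of 10000 random lists of the same size matched on mean intensity, in 20 bins, as a description of these arrays. Lists share members, and each member counts in every list that holds it.

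The calls and percentiles were tested on simulated data with known changes. Changes were planted on the IL-6/TGFβ array alone, in genes whose mean lay more than 2-fold above the floor. Noise was near the size of the probe-set spread. Recovery of genes near the floor, and differences between cultures or arrays, were therefore not tested. For IL-6/TGFβ over TGFβ, over 9374 genes, 99% of changes of 1.5 log2 units and 100% of changes of 3 log2 units were called, and 0 unchanged genes. For IL-6/TGFβ over IL-6/IL-23, over as many genes, 92% and 98% were called, and 6 unchanged genes. Of 40 unchanged lists, 4 and 2 in these comparisons lay outside the central 95% of random lists.

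These alternative settings were median scaling, unscaled values, cyclic loess, a floor divided or multiplied by 2, a pseudocount in place of the floor, the mean of a gene's probe sets, probe sets without the suffixes that mark possible cross-hybridization, and size rules of 1.5-fold and 3-fold. Added after the data were seen were a floor without the thyroglobulin gene Tg, a normalization without the IL-6/IL-23 array, and the counts of genes shared with IL-6/IL-23 over TGFβ. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Genes of the lists with no probe set of 1 gene symbol were not analysed here.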

Results

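Gene expression was compared between CD4+CD25- T cells of Stat6 and T-bet double-deficient mice, activated for 2 days with TGFβ, with IL-6 and IL-23, or with IL-6 and TGFβ. The conditions have 1 array each and no replicates, so ratios below describe 3 arrays and carry no p-value. Levels are quantile-normalized intensities, given in the order TGFβ, IL-6/IL-23, IL-6/TGFβ, and ratios are on the log2 scale. Of 18193 named genes, 9136, 9306 and 9243 were above the floor on these arrays. The IL-6/IL-23 array was the dimmest as deposited, and the 3'/5' ratio of the transferrin receptor control probe sets was 2.53, 2.65 and 2.49.

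Both deleted genes gave signal above the floor on every array. Stat6 read 259, 191 and 223, and Tbx21 read 190, 205 and 118. The labels do not say which part of either gene was deleted, and a probe set outside the deleted part checks nothing. General T cell genes were at similar levels. Of 12 measured T cell identity genes none was 2-fold apart in either comparison with the IL-6/TGFβ array, and Cd28, a costimulatory receptor, was the 1 gene of this list that was higher on the IL-6/IL-23 array than on the TGFβ array (1.59). Cd4 itself read 1333, 904 and 716.

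The IL-6/TGFβ array was first set against the TGFβ array, which the study used to find genes of Th17 polarization that go with both IL-17 and IL-10. Il10, the gene of the anti-inflammatory cytokine IL-10, read 62.8 with TGFβ and 1012 with IL-6/TGFβ, a 16.1-fold higher level. Il17a, the signature cytokine of Th17 cells, read 498 and 3210 (6.44-fold). Il21, a cytokine that sustains Th17 cells, was at the floor with TGFβ and read 2325 with IL-6/TGFβ, at least 50-fold higher. The transcription factors Maf (2.09) and Ahr (2.03) were also higher with IL-6/TGFβ, and 4 probe sets of Maf lay between 2.09 and 2.72. Socs3, the feedback inhibitor of IL-6 signalling, was 7.25-fold higher, and Nfil3, a transcription factor gene, was 6.79-fold higher.

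Over all genes, 272 were at least 2-fold higher and 215 at least 2-fold lower on the IL-6/TGFβ array than on the TGFβ array. Among genes measured on both arrays, the largest ratios were those of Tgm2, which encodes a transglutaminase (5.92), Timp1, an inhibitor of matrix metalloproteinases (5.00), Il10 (4.01), Frmd4b (3.52), Stard10 (3.21), Plac8 (3.06), the chemokine receptor Cxcr4 (3.06), the leukotriene receptor Cysltr1 (3.05), Pou2af1 (2.98) and Socs3 (2.86). After Il21, the largest bounds were at least 25.5-fold for Serpinb1a, an inhibitor of neutrophil proteases, 17.2-fold for Tox2, 6.98-fold for Lgr4 and 6.63-fold for Ppm1j. The lowest ratios were those of Tnfsf11, which encodes the cytokine RANKL (-4.72), Nrp1 (-3.67), the activation-induced nuclear receptor Nr4a3 (-2.77), the chemokine Ccl3 (-2.68), Dapl1 (-2.64), Igfbp7 (-2.53), Cd274, which encodes PD-L1 (-2.52), Tesk2 (-2.31), Mndal (-2.30) and St8sia6 (-2.30). Lad1 was at least 44.7-fold lower, Serpinb6b at least 7.59-fold, the granzyme B inhibitor Serpinb9 at least 7.14-fold, Sntb1 at least 6.15-fold, and Gata3, the transcription factor of Th2 cells, at least 5.55-fold lower.

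Of 17 measured IL-6 and STAT3 response genes, 8 were higher with IL-6/TGFβ than with TGFβ and 0 were lower, with a median ratio of 0.77 at percentile 100 of the random lists. They included Socs3, Il21, the receptor gene Il4ra (1.89) and the transcription factor Batf (1.60). Of 13 measured Th17 genes 6 were higher and 2 lower (median 0.83, percentile 100), and of 18 genes of IL-10 and its reported regulators 6 were higher and 1 lower (median 0.30, percentile 99.99). The lower member of the regulators was Gata3. Of 5 measured aryl hydrocarbon receptor targets, 3 were higher and 0 lower (median 1.89, percentile 100). These were Ahr itself, Tiparp (2.28) and the cytochrome P450 gene Cyp1b1, at the floor on the TGFβ array and at least 3.69-fold higher.

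Genes of other T cell programmes were lower or mixed in this comparison. Of 17 regulatory T cell genes 2 were higher and 4 lower (median -0.25, percentile 0.44), and Foxp3, the transcription factor of regulatory T cells, read 498 with TGFβ and 232 with IL-6/TGFβ (-1.10). Nrp1 and Tnfrsf18 (-1.39) were lower in the same list, while Il10 and Ctla4 (1.36) were higher. Of 11 Th1 genes 1 was higher and 2 were lower (median -0.54, percentile 0.02), with Eomes at least 2.30-fold lower, Il18r1 at -1.20 and Runx3 at 1.06. The Th1 list counts Tbx21, a gene deleted in these mice, in every comparison (-0.69 here and -0.80 over IL-6/IL-23). Of 19 T cell activation genes 0 were higher and 4 lower (median -0.13, percentile 3.48), led by Nr4a3, Egr3 (-1.75), Tnfrsf9 (-1.43) and Nr4a1 (-1.09). Of 21 glycolysis and hypoxia genes, 2 were higher and 0 lower (median 0.22, percentile 99.84). These were Bnip3 (1.55) and Hif1a (1.08), the oxygen-regulated transcription factor. In every comparison this list also counts Pigq, which a synonym matched in place of Gpi1 and which is not a glycolysis gene. Of 18 cholesterol synthesis genes, 0 were higher and 0 lower (median -0.26, percentile 0.15).

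Of 5 measured CD8 T cell and NK cell markers 0 were higher and 1 was lower, Eomes, with a median of -0.43 at percentile 1.10 that lay outside the central 95% of random lists in 5 of 9 settings, and Cd8a read 145 with TGFβ and 80.2 with IL-6/TGFβ (-0.85). Of 4 measured myeloid markers 1 was lower (median -0.27, percentile 5.99). This was Mpeg1, a macrophage gene, at the floor on the IL-6/TGFβ array and at least 3.29-fold lower. Of 6 cytotoxic effector genes 0 were higher and 2 lower (median -0.34, percentile 1.42), namely Nkg7 (-2.16) and Gzmb, the gene of granzyme B (-1.34), and this list too lay outside in 5 of 9 settings.

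The size rule counted 487 genes, or 4.92% of 9895, against at most 6 per direction in unchanged arrays simulated with the probe-set spread of 0.23. Where the brightest probe set was 2-fold apart, a further probe set had the same sign in 97.9% of 144 genes. It went the same way by at least 0.5 log2 units in 84.7% of them. Scaling set the balance of the counts: 55.9% of them were higher after quantile normalization, 43.9% after median scaling (207 higher, 264 lower), which moves the median ratio of genes measured on both arrays to -0.08, and 15.1% without scaling (126 higher, 706 lower).

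**Figure D1:**
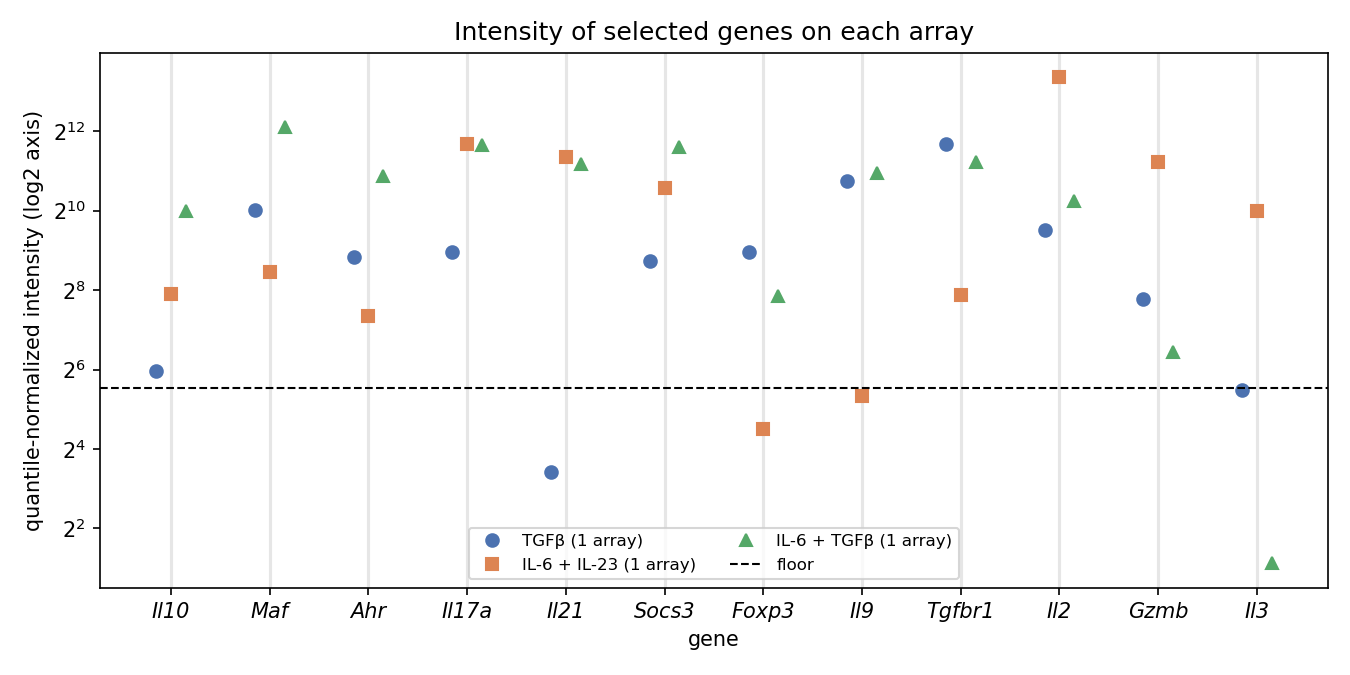
Normalized intensity on a log2 axis of 12 genes on each of the 3 arrays, with 1 array per condition and therefore no error bars, and the floor of 46.5 as a dashed line. Il10, Maf and Ahr were brightest on the IL-6/TGFβ array, Il17a and Il21 were bright on both IL-6 arrays, Foxp3 and Il9 were at the floor on the IL-6/IL-23 array, and Il2, Gzmb and Il3 were brightest there.

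The IL-6/TGFβ array was next set against the IL-6/IL-23 array, a comparison the study used to set aside genes tied to IL-17 alone. Il17a was at nearly the same level on both, 3210 and 3273 (-0.03), and Il21 differed little (-0.18). Il10 was 4.22-fold higher with IL-6/TGFβ (1012 against 240). Maf read 4388 against 351 (3.65, with 4 probe sets between 3.23 and 3.65), and Ahr read 1861 against 163 (3.51). Foxp3 was at the floor with IL-6/IL-23 and at least 4.99-fold higher with IL-6/TGFβ. Il2, the main T cell growth factor, read 1208 with IL-6/TGFβ and 10464 with IL-6/IL-23 (-3.11).

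In this pair 387 genes were at least 2-fold higher and 363 at least 2-fold lower on the IL-6/TGFβ array. The largest ratios measured on both arrays were those of Ctla2b (5.50) and Ctla2a (5.06), inhibitors of cysteine proteases, the kinase Sgk1 (4.86), Cxcr4 (3.68), Maf, Stard10 (3.55), Ahr, Kctd14 (3.50), the prion protein gene Prnp (3.40) and the glycoprotein gene Pdpn (3.38). Ctla2a and Ctla2b are near-identical paralogs, so the values within this pair are uncertain. Ifitm2 and Ifitm3, of 1 gene family, had opposite signs for IL-6/TGFβ over TGFβ (-1.63 and 0.64), and cross-hybridization between them was not tested. The largest bounds were at least 58.0-fold for the protease gene Ctsw, 42.5-fold for the cytokine Il9, 33.2-fold for the water channel Aqp3, 25.5-fold for Serpinb1a and 12.1-fold for Nipal1. The lowest ratios were those of Gzmb (-4.78), the interferon-induced genes Ifitm3 (-4.40) and Ifitm2 (-3.35), Nrn1 (-3.93), Ccl3 (-3.56), the viral RNA sensor Ifih1 (-3.53), the activin subunit Inhba (-3.35), Snx9 (-3.27), Tnfsf11 (-3.26) and Id3 (-3.14). Serpinb9 was at least 29.3-fold lower with IL-6/TGFβ, Lum at least 27.1-fold, the cytokine Il3 at least 21.8-fold, Serpinb6b at least 15.2-fold and Tg at least 14.7-fold lower.

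Of 18 measured TGFβ response genes, 9 were higher with IL-6/TGFβ than with IL-6/IL-23 and 1 was lower (median 1.06, percentile 100). Ldlrad4, an inhibitor of TGFβ signalling, was at least 10.7-fold higher, the receptor Tgfbr1 stood at 3.34, and Id3 was the lower member. Of 17 regulatory T cell genes, 8 were higher and 3 lower (median 0.91, percentile 100). The higher ones included the ectoenzyme genes Nt5e (at least 9.82-fold) and Entpd1 (at least 7.98-fold) and Socs2 (2.65). Of 5 aryl hydrocarbon receptor targets, 3 were higher and 0 lower (median 1.21, percentile 100), namely Ahr, Cyp1b1 (at least 3.69-fold) and Cyp1a1 (at least 2.31-fold). Of 9 Th2 genes 4 were higher and 3 lower (median 0.73, percentile 99.96). The higher ones included Il9 and the chemokine receptor Ccr8 (at least 11.6-fold), and the lower ones Il13 (at least 5.44-fold) and Gata3 (at least 2.58-fold). Of 18 chemokines and their receptors 5 were higher and 5 lower (median 0.65, percentile 100), with Cxcr4, Ccr8 and Ccl20 (at least 8.94-fold) higher and Ccl3 lower.

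Of 19 T cell activation genes 0 were higher with IL-6/TGFβ than with IL-6/IL-23 and 7 were lower (median -0.81, percentile 0), among them Il2, Nr4a2 (-1.74), Tnfrsf4 (-1.46) and Tnfrsf9 (-1.17). Of 11 Th1 genes 0 were higher and 4 lower (median -0.78, percentile 0.02), which were the chemokine receptor Cxcr3 (-2.05), Ifng, the gene of interferon-γ (-1.63), Stat4 (-1.33) and Il12rb2 (at least 2.18-fold lower). Of 9 follicular helper genes 1 was higher and 3 were lower (median -0.81, percentile 0.02), with Cxcr5 at 2.34 and Btla at -2.02, Cd200 at -1.60 and Sh2d1a at -1.48. Of 19 stress and heat shock genes 1 was higher and 4 were lower (median -0.43, percentile 0.05), with Jun at 1.57, Atf3 at -2.29 and Hspa1b at least 3.77-fold lower. Of 18 cholesterol synthesis genes 0 were higher and 1 was lower, Lss (-1.08), with a median of -0.37 at percentile 0.20. Of 14 naive and resting T cell genes 2 were higher and 0 lower (median 0.50, percentile 99.99), namely Klf2 (1.88) and Foxo1 (1.15). Beside the lower Gzmb, the 5 CD8 T cell and NK cell markers had a median of -0.49 at percentile 3.39, with 0 higher and 0 lower, and Cd8b1 read 104 with IL-6/TGFβ and 174 with IL-6/IL-23 (-0.74).

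Lists named for IL-17 and IL-10 did not stand apart from random lists as a whole. Of 13 Th17 genes 5 were higher and 4 lower (median -0.03, percentile 52.3), with Maf, Ahr and Ccl20 higher and Tnfsf11 lower. Of 18 genes of IL-10 and its reported regulators 5 were higher, Il10 itself among them, and 2 lower (median 0.02, percentile 72.3). Of 17 IL-6 and STAT3 response genes 3 were higher and 1 was lower (median 0.05, percentile 77.2). The 3 were Il6st, the shared receptor chain of the IL-6 family (1.77), Il4ra (1.06) and Socs3 (1.03), and the lower gene was Fos (-1.46). A further probe set of Il4ra gave 0.09.

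Together 750 genes, or 7.58% of 9895, passed the size rule, against at most 15 per direction in simulated unchanged arrays with a probe-set spread of 0.29. In 225 genes the brightest probe set was 2-fold apart and a further one could be read. The further one had the same sign in 95.1% of them, and by at least 0.5 log2 units in 79.1%. The conditions differed in both TGFβ and IL-23, so no ratio here belongs to either cytokine alone. After quantile normalization 51.6% of the 750 genes were higher. The share was 37.3% after median scaling (302 higher, 507 lower, with the median ratio of genes measured on both arrays at -0.21), and 89.4% without scaling (1100 higher, 131 lower). The Th2 list's excess over random lists turned to -0.0080 with the mean of a gene's probe sets.

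**Figure D2:**
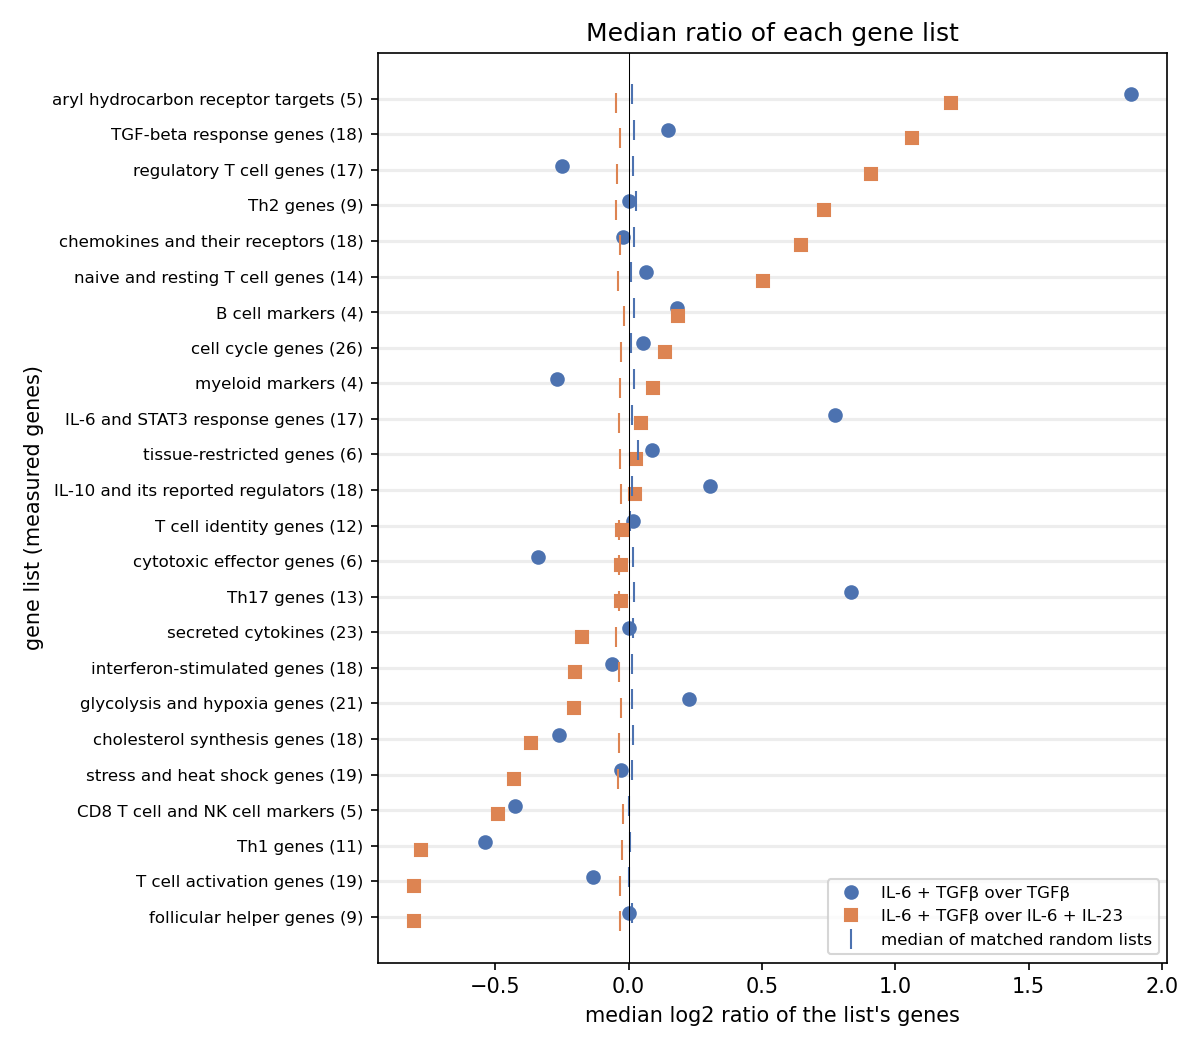
Median log2 ratio of each gene list with at least 4 measured genes, for IL-6/TGFβ over TGFβ (circles) and over IL-6/IL-23 (squares), with the median of matched random lists as a tick and the number of measured genes in brackets. A gene at the floor on both arrays of a pair entered as 0, and medians of exactly 0 rest on such genes. TGFβ response genes had medians of 0.15 and 1.06, and IL-6 and STAT3 response genes medians of 0.77 and 0.05.

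The filter for IL-10 genes that the study describes joins both comparisons. Applied with the normalization, floor and 2-fold rule used here, it kept 134 genes higher and 72 lower with IL-6/TGFβ than on either other array. Il10 itself passed, as did Maf and Ahr. Others were Serpinb1a (at least 25.5-fold in both), Stard10 (3.21 and 3.55), Cxcr4 (3.06 and 3.68), Tox2 (at least 17.2-fold, and 2.92), Basp1 (2.85 and 3.29), Pdpn (2.70 and 3.38), Olfm2 (at least 6.23-fold in both), Gcnt2 (at least 6.18-fold in both), Pltp (2.48, and at least 10.5-fold) and Lbp (at least 5.51-fold in both). Sgk1, Ctla2a, Ctla2b, Aqp3, Cxcr5, Il6st, Il4ra and Socs3 were also among the 134. Il17a, Il21, Timp1, Tgm2 and Nfil3 passed the first comparison and not the other.

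The genes lower in both comparisons included Tnfsf11, which read 1634, 596 and 62.1. Others were Serpinb6b and Serpinb9, which were at the floor on the IL-6/TGFβ array, Ccl3, Cd274 (-2.52 and -2.48), Trat1 (at least 5.02-fold and 4.57-fold lower), Glipr1 (-2.03 and -2.04), the guanylate-binding protein gene Gbp6 (-1.99 in both), Tacc2 (-1.87 and -2.10) and Spin4 (at least 3.65-fold and 7.62-fold lower). For Glipr1 a further probe set gave -0.65 and 0.03. Gata3, Gzmb and Tnfrsf18 were lower in both as well.

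Because both comparisons share the IL-6/TGFβ array, some overlap arises with no effect. Simulated unchanged arrays gave at most 2 genes higher and 1 lower in both, and independent lists of these sizes would share 10.6 and 7.89. The correlation of ratios across genes was 0.45, against 0.35 in unchanged arrays (highest 0.38), and the covariance was 0.140 against 0.0244, a difference of 0.116. The unchanged arrays held normal probe-set noise alone, without outlying probe sets, so exceeding them shows only differences larger than that noise. Arrays that truly differ would also give overlap and correlation through the shared array, so no excess beyond sharing can be read from these values. By the same rule 199 genes were higher on the IL-6/IL-23 array than on both others. Genes are not independent replicates, and a single shared array cannot be split, so part or all of the excess may come from it. Median scaling gave joint counts of 100 higher and 102 lower, of which 100 and 72 were among the genes counted here, and Socs3 was then below 2-fold over IL-6/IL-23 (0.78). Without scaling the counts were 88 and 64, of which 72 and 40 were among them.

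**Figure D3:**
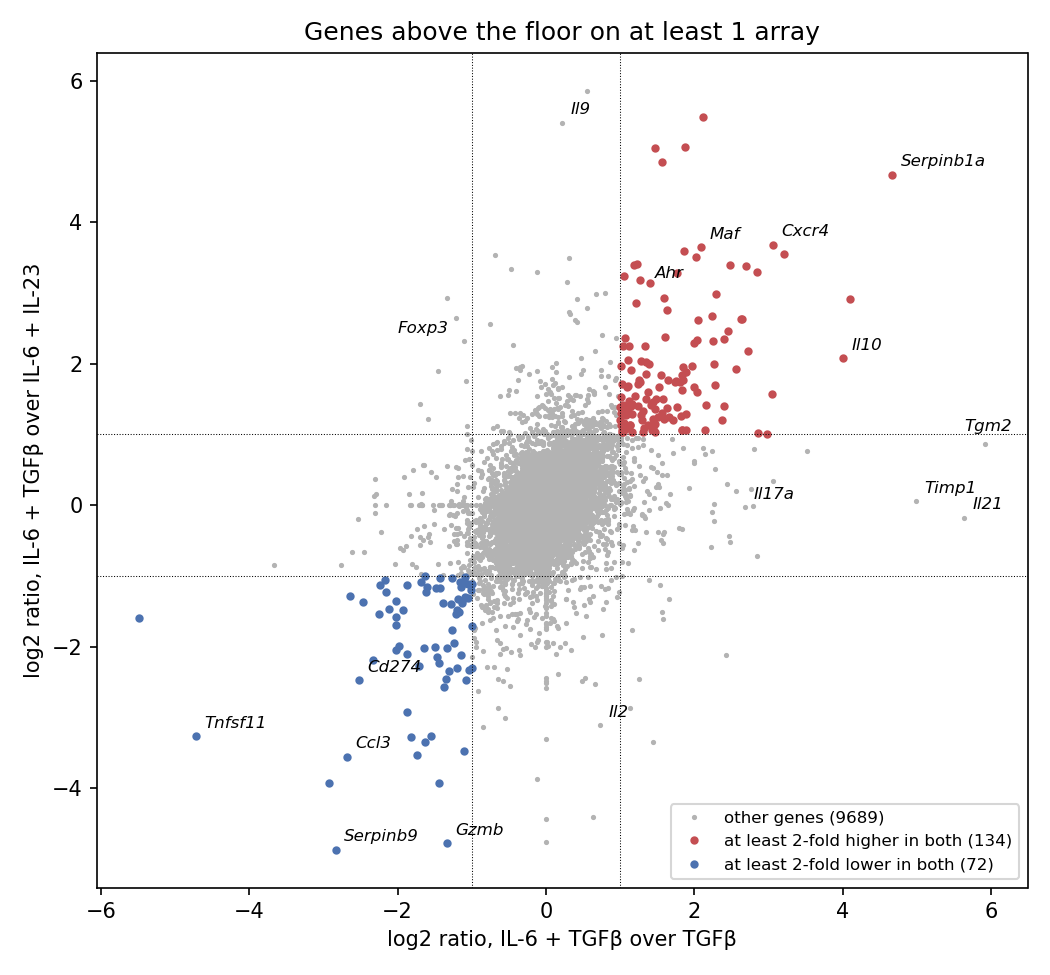
Each point is a gene above the floor on at least 1 array (9895 genes), with its log2 ratio for IL-6/TGFβ over TGFβ on the horizontal axis and over IL-6/IL-23 on the vertical axis, and dotted lines at 2-fold. The 134 genes higher in both, among them Il10, Maf and Ahr, lie at the upper right, the 72 lower in both at the lower left, and Il17a, Il21 and Timp1 near 0 on the vertical axis.

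The remaining pair set IL-6/IL-23 against TGFβ. Il17a (6.57-fold) and Il10 (3.82-fold, 240 against 62.8) were higher with IL-6/IL-23, and Il21 was at least 56.5-fold higher. Maf (-1.56) and Ahr (-1.48) were lower there than with TGFβ. Foxp3 was at the floor with IL-6/IL-23 and at least 10.7-fold lower, and Il9 at least 36.6-fold lower. The largest ratios measured on both arrays were those of Tgm2 (5.06), Ifitm3 (5.04), Timp1 (4.94), Inhba (4.80) and the integrin gene Itga3 (4.54), and the lowest those of Tbc1d4 (-4.27, with a further probe set at -0.94), Lad1 (-3.88), Socs2 (-3.86), Tgfbr1 (-3.81) and Ctla2b (-3.37).

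In this pair 367 genes were higher and 340 lower. Of 272 genes higher with IL-6/TGFβ than with TGFβ, 91 were also higher with IL-6/IL-23 than with TGFβ and 84 of these were not higher in the comparison of both IL-6 arrays (28 without scaling and 55 with a pseudocount), while 127 were higher over IL-6/IL-23 and not in this pair, 7 passed all 3 comparisons and 54 passed neither of the others. Il10, Cysltr1 and Tox2 were among those higher in all 3. Secreted cytokines had a median of 0.87 at percentile 100, with 11 of 23 higher and 5 lower. Il2 (3.85), Il3 (at least 21.8-fold), Il13 (at least 5.44-fold), Il4 (1.77), Csf2 (1.05) and Il5 (at least 2.43-fold) were higher with IL-6/IL-23, and Il9 and Lta (-2.34) were lower. Several of these cytokines were named after their values were seen. With IL-6/TGFβ over TGFβ, 4 of these 23 cytokines were higher and 2 lower, with the middle one at the floor on both arrays, and over IL-6/IL-23 5 were higher and 8 lower (median -0.18, percentile 11.8).

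TGFβ response genes (2 higher, 8 lower, median -0.83, percentile 0) and regulatory T cell genes (2 higher, 10 lower, median -1.39, percentile 0) were lower with IL-6/IL-23 than with TGFβ. Higher were IL-6 and STAT3 response genes (6 higher, 1 lower, median 0.83, percentile 100), follicular helper genes (5 higher, 0 lower, median 1.00, percentile 100), and glycolysis and hypoxia genes (6 higher, 0 lower, median 0.64, percentile 100), with Bnip3 at 2.05 and the glucose transporter Slc2a3 at 2.07. Stress and heat shock genes had 4 higher and 0 lower (median 0.37, percentile 99.68), and Th1 genes 3 higher and 0 lower (median 0.34, percentile 96.2). Th17 genes had 6 higher and 5 lower (median 0.56, percentile 99.98), and Th2 genes 4 higher and 3 lower (median 0.83, percentile 99.98). Activation genes had 2 higher and 1 lower (median 0.24, percentile 98.3), and naive and resting T cell genes 3 higher and 2 lower (median -0.35, percentile 0.14). Chemokines and their receptors had 3 higher and 5 lower (median -0.15, percentile 1.76). Beside them, 1 of 4 myeloid markers, Mpeg1, was at least 3.29-fold lower with IL-6/IL-23 (median -0.58, percentile 0.81), and the macrophage and T cell protease gene Ctss stood at -0.72. The 707 genes counted compare with at most 18 per direction in simulated unchanged arrays, with a probe-set spread of 0.31. In 228 genes the brightest probe set was 2-fold apart and a further one could be read. The further one had the same sign in 93.0% of them, and by at least 0.5 log2 units in 78.9%. With the mean of a gene's probe sets the excess over random lists turned to -0.086 for Th17 genes and to 0.17 for naive and resting T cell genes, and without scaling 81 genes were higher and 3311 lower, or 2.39% against 51.9% higher.

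Of 26 cell cycle genes 0 were 2-fold apart in any of the 3 comparisons, with a median of 0.05 (percentile 78.5) for IL-6/TGFβ over TGFβ and 0.14 (percentile 98.4) over IL-6/IL-23, where Mki67 stood at 0.76. Of 18 interferon-stimulated genes, 2 were lower with IL-6/TGFβ than with TGFβ (Ifih1 and Usp18, -1.05) and 2 lower than with IL-6/IL-23 (Ifih1 and Oas3, at least 2.74-fold), 0 were higher, and the medians were -0.06 (percentile 14.5) and -0.20 (percentile 6.57), while 3 were higher and 0 lower with IL-6/IL-23 than with TGFβ. Medians of the remaining lists for IL-6/TGFβ over TGFβ were 0.07 for naive and resting T cell genes (percentile 73.7; 3 higher, 1 lower), -0.02 for chemokines and their receptors (19.9; 2 higher, 5 lower), 0.15 for TGFβ response genes (91.5; 2 higher, 1 lower), -0.03 for stress and heat shock genes (20.2) and 0.02 for T cell identity genes (55.5), with 0 higher and 0 lower in these last lists. Of 9 Th2 genes 2 were higher and 1 lower, and of 9 follicular helper genes 3 were higher and 1 lower, with no median given because the middle gene of each list was at the floor on both arrays. Over IL-6/IL-23 they were -0.21 for glycolysis and hypoxia genes (percentile 2.88), with Slc2a3 (-2.55) the 1 lower gene, -0.03 for cytotoxic effector genes (51.3; 1 higher, 1 lower), -0.02 for T cell identity genes (53.9) and 0.09 for myeloid markers (72.9).

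Most markers of other cell types were at the floor on every array. Of 12 B cell markers fixed, 4 were above it on some array, with medians of 0.18 (percentile 91.4) and 0.19 (percentile 91.4) in the comparisons with the IL-6/TGFβ array, and Cd74, an antigen presentation gene, read 181, 133 and 245. Cd79a, Cd79b and Pax5 were at the floor on every array. The immunoglobulin genes Igkv8-30 (1.89 and 1.29) and Igha (1.84 and 1.06), picked after their values were seen, were higher in both comparisons. Ighm was not (-0.64 and 0.09), and B cells as a source of the 134 genes were not tested. Above the floor on at least 1 array were 1 dendritic cell marker (Ccl17), 1 gamma-delta T cell marker (Trgv4), 1 mast cell and basophil marker (Kit, which read 110, 16.3 and 75.9) and 2 erythroid and platelet markers (Epor and Itga2b), too few for a median. None of 3 Y-linked genes on the array was above it. Of 51 tissue-restricted genes, which set the floor, 6 were above it on some array, with medians of 0.09 (percentile 67.0) and 0.03 (percentile 67.8). Among them Tg read 683 on the IL-6/IL-23 array against 50.6 with TGFβ, and Myh7 read 145, 189 and 30.3.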

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

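Tests of array brightness, mast cell markers, CD8 markers and RNA degradation, and the counts under other settings given here, were chosen after the results they bear on were seen, while the tests of probe set noise were written before. Among the 9160 probe sets with no gene name here, 1572 were above the floor on at least 1 array. Of these, 13 were at least 2-fold higher on the IL-6/TGFβ array than on both others, with the largest at 2.85 by its smaller log2 ratio, and 6 were lower. They drew attention as signal in data outside the comparisons of named genes.

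A set of 9 genes was at the floor with IL-6/IL-23 and at least 4-fold higher on both arrays with TGFβ, namely Foxp3, Il9, Ctsw, Aqp3, Ccr8, Ccl20, Entpd1, Nt5e and Ldlrad4. Membership depended on the floor and on the choice of probe set: 2 of the 9 remained with the floor divided by 2, 5 with it multiplied by 2, 7 with a pseudocount, 5 with the mean of probe sets and 6 without cross-hybridizing ones, while all 9 remained under the other 3 scalings, among 23 such genes without scaling. A dimmer IL-6/IL-23 array is argued against only by the size of its array-wide shift. Of 5090 other genes in the same range of deposited intensity, 1.08% were at least 4-fold lower on it in deposited values. Their median fall was 0.44 log2 units. The array-wide shift was known before this test, so a low share was largely fixed in advance. Mast cells or basophils, which can express Il9, are also argued against, since 1 of 6 of their markers was above the floor on an array with TGFβ, and Cpa3, an abundant mast cell gene, was at the floor on all 3. The 1 marker, Kit (110, 16.3 and 75.9), was above the floor on both arrays with TGFβ and at it with IL-6/IL-23, as this explanation calls for, while the other 5 were not. A biological hypothesis is that these genes may need TGFβ in these cells. It remains untested, because the array without TGFβ is also the one with IL-23 and each condition has 1 culture. Replicate cultures with IL-6 alone, and with TGFβ added to IL-6/IL-23, would test it.

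Another 199 genes were at least 2-fold higher with IL-6/IL-23 than on both other arrays, among them Il2, Il3, Gzmb, Ifitm3 and Inhba. This count depended on scaling and on the floor: it was 233 with median scaling, 203 with cyclic loess and 42 without scaling, where this array was the dimmest, and all 42 were among the 199. It was 276 with the floor divided by 2, 134 with it multiplied by 2 and 129 with a pseudocount. Probe set noise is argued against, since 82.5% of 40 further probe sets (33) were also higher there by at least 0.5 log2 units. RNA degradation is argued against as well, since the 3'/5' control ratio on this array was 1.06 times the lower of the others. CD8 T cells or NK cells stay open despite the CD4+ gate: Cd8b1 was 0.32 log2 units higher there than on the brighter of the other arrays and 0.74 higher than on the dimmer, short of 2-fold by less than the spread of 0.29, while Cd8a (145, 120 and 80.2) was lower there than with TGFβ. Neither marker reached the 2-fold excess over both other arrays that this explanation calls for. Presence of IL-23 and absence of TGFβ could each underlie the pattern and were not separated by the design; the cultures named above would separate them.

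For the 134 genes higher with IL-6/TGFβ than on both other arrays, simulated unchanged arrays gave at most 2 such genes. Their noise was normal and held no outlying probe sets, so a low count was largely fixed in advance. Of 37 further probe sets of the 134 genes, 81.1% were higher in both comparisons by at least 0.5 log2 units. For the genes with a further probe set, this argues against probe set noise on the shared array. A difference between single cultures unrelated to the cytokines cannot be told apart from a cytokine effect, because there was 1 array per condition. A joint action of IL-6 and TGFβ on Maf, Ahr and Il10 may be a hypothesis for new cultures. It was not tested, because no array had IL-6 alone, and replicate cultures with IL-6 alone would be needed. With IL-6/IL-23, Il10 was already higher than with TGFβ (1.94), while Maf (-1.56) and Ahr (-1.48) were lower.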

How the results depend on the processing

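The added settings (floor without Tg, IL-6/IL-23 array left out of the normalization) and the counts shared with IL-6/IL-23 over TGFβ were chosen after the data were seen; the others were planned. Of the counts and correlations of the comparisons under the alternatives, 73 stayed within 1.5 times, or within the spread for the correlation, and 37 moved. A count that stayed can still hold other genes. With the mean of a gene's probe sets, 91 of the 134 joint higher and 51 of the 72 joint lower genes remained. So did 244 of 387 genes higher over IL-6/IL-23, and 206 of 340 lower for IL-6/IL-23 over TGFβ. Of values of single named genes, 1120 differed by less than the probe-set spread, 490 by more, and 0 changed direction. Of list medians relative to random lists, 557 stayed and 49 moved, some of them with a change of sign in lists that lay inside the central 95% of random lists. Of the lists outside it, 3 changed sign, all with the mean of a gene's probe sets: Th17 genes (-0.086) and naive and resting T cell genes (0.17) for IL-6/IL-23 over TGFβ, and Th2 genes (-0.0080) for IL-6/TGFβ over IL-6/IL-23. For IL-6/TGFβ over TGFβ, the CD8 and NK cell list and the cytotoxic list lay outside the central 95% of random lists in 5 of 9 settings each. Regulatory T cell and Th1 genes did so in 8 of 9 there. Over IL-6/IL-23, Th2 and naive genes did so in 8 of 9. For IL-6/IL-23 over TGFβ, activation genes did so in 7 of 9, and Th17, Th2, chemokine, naive and myeloid lists in 8 of 9. B cell markers under 3 settings, and myeloid markers under 1, had too few genes for a value.

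Without scaling, higher and lower counts were 126 and 706 for IL-6/TGFβ over TGFβ, 1100 and 131 over IL-6/IL-23, and 81 and 3311 for IL-6/IL-23 over TGFβ. The joint higher count was 88, the correlation 0.40, and the count higher in both comparisons with TGFβ but not between the IL-6 arrays 28; the array-wide shifts of -0.41, 0.54 and -0.96 log2 units account for the direction. With the 1.5-fold rule, which admits more genes by construction, they were 784 and 665, 1029 and 1079, and 1038 and 876, with 379 and 266 joint genes and 255 shared with IL-6/IL-23. With the 3-fold rule they were 97 and 73, 133 and 121, and 139 and 107, with 43 and 17 joint genes and 29 shared. A pseudocount gave 139 lower with IL-6/TGFβ than with TGFβ, 45 joint lower and 55 shared genes, and a doubled floor 45 joint lower genes. The correlation was 0.44 with median scaling, 0.44 with cyclic loess, 0.47 and 0.44 with the floor divided or multiplied by 2, 0.46 with the mean of probe sets and 0.45 without cross-hybridizing probe sets. Causes of these other moves were not tested. No paired analysis was possible because each condition had 1 array. Signal over background limits genes near the floor: 45 of the 272 higher and 50 of the 215 lower genes of the first comparison had 1 array at the floor.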

Other observations

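The gene families below were chosen after their values were seen, and no explanation of them was tested. Metallothioneins, which bind zinc and other metals, were higher on both IL-6 arrays than on the TGFβ array. Mt1 stood at 1.58 for IL-6/TGFβ over TGFβ and at 3.18 for IL-6/IL-23 over TGFβ, and Mt2 at 3.57 in the latter. Between the IL-6 arrays Mt1 was lower with IL-6/TGFβ (-1.60), and Mt2 was lower by less than 2-fold (-0.72). These directions held under the other 3 scalings, with Mt1 between 2.27 and 3.28 for IL-6/IL-23 over TGFβ. The calcium-binding protein gene S100a6 followed the same order, at 1.66, 2.99 and -1.33. Of 6 S100a genes above the floor, it was the only 1 at least 2-fold apart in any of these comparisons.

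Guanylate-binding proteins, interferon-induced GTPases of host defence, had 6 members above the floor. Of these, Gbp6 (-1.99), Gbp7 (-2.29) and Gbp8 (-1.84) were at least 2-fold lower with IL-6/TGFβ than with IL-6/IL-23, and this direction held under every scaling tried. Gbp2b (-0.79) was also lower, between -1.13 and -0.48 under the other scalings. Gbp2 (-0.14) and Gbp3 (-0.21) were less than 2-fold apart, and their sign turned without scaling. Of 5 Serpinb genes above the floor, Serpinb1a was higher and Serpinb6b and Serpinb9 were lower with IL-6/TGFβ than on both other arrays under every scaling tried, while Serpinb6a and Serpinb6e were less than 2-fold apart in these comparisons.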
